A study of Mus musculus with 8 samples.

How the data were processed

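The samples were mouse splenic CD4 T cells, taken at 10 weeks of age per the labels, polarized in culture and harvested at day 3. Cells came from wild-type mice (WT) or from mice lacking Gpr65 (KO), and were cultured under Th17 or Th22 conditions, with 2 libraries in each of the 4 groups. Th17 cultures received IL-1b and IL-23 at 20 ng/ml each and IL-6 at 25 ng/ml. Th22 cultures received the same IL-1b and IL-23, IL-6 at 40 ng/ml and FICZ, a ligand of the aryl hydrocarbon receptor, at 400 nM. The Th22 and Th17 conditions therefore differed in both FICZ and the IL-6 dose. Libraries were made with the 10x Genomics Chromium 3' kit, which tags each captured mRNA with a unique molecular identifier (UMI) near its 3' end. The labels number the libraries of a group 1 and 2 without saying whether they came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be partly technical.

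The deposited matrix held UMI counts per gene and cell, unnormalized, for all 8 libraries together, and each cell name and a deposited cell table gave its library. Cell Ranger 5.0.1, Seurat and the genome build mm10 are named in the submitters' processing notes, without the step each was used for. The matrix held 16649 gene symbols and 104660 cells with 354411580 UMIs, and the deposited total count and number of detected genes matched the matrix in all 104660 cells. The deposited table also gave, per cell, the percent of UMIs from mitochondrial genes, which reached 9.99 at most, a score for the S phase and a score for the G2/M phase, and a cluster number. No cell had fewer than 201 genes or more than 9999 UMIs. How the authors set such limits, computed the scores or made the clusters is not given in the sources used here. The deposited scores were not used, and the phase of each cell was called anew from fixed S and G2/M lists.

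Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left 101688 cells and removed 2972. The kept cells held between 33826527 UMIs (WT Th17 replicate 1) and 58895019 UMIs (KO Th22 replicate 2) per library, a ratio of 1.74. Scrublet was run per library through scanpy with an expected doublet share of 8% and marked 2 of the kept cells, so it did not work on these data. Doublets were therefore not removed, and the 8% of cells with the most UMIs in each library, 8133 cells, were left out as an alternative. Gene symbols were matched to a GENCODE annotation of mm10 for positions only, and 98.3% of the symbols matched 1 gene. The files give symbols without identifiers, so identifiers and coordinates come from that match.

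Counts were summed over the cells of each library, and the sums were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, genes kept by filterByExpr on the 4 groups, robust estimation and Benjamini-Hochberg adjustment at 0.05. This left 13412 genes. KO was compared with WT in Th17 and in Th22, Th22 with Th17 in WT and in KO, and the interaction was tested, all in a model with 1 mean per group and 4 residual degrees of freedom. The genotype effect over both polarizations and the polarization effect over both genotypes came from an additive model with 5 residual degrees of freedom. CPM values were computed here from the deposited counts, relative to each library's total after TMM scaling. Log2 fold changes are given with the standard error implied by the test.

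Before the data were examined, 39 gene lists were fixed for T helper programs, cytokine and stress responses, metabolism, cell cycle and other cell types. The 36 lists with at least 3 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. The rule for named genes was fixed at the same time. Per comparison it takes the 10 largest rises and the 10 largest falls among genes that passed the test, with a mean of at least 10 CPM and no overlap between the libraries of the sides compared. It adds up to 4 members with the smallest adjusted p of each list described, and Gpr65, Il17a, Il17f, Il22, Ahr, Cyp1a1, Ifng, Csf2, Il10, Foxp3, Tbx21, Il23r, Gzmb, Tnf and Il2. Gene models without a name and variable segments of antigen receptors were counted and not named. Some genes that this rule takes are not reported here. Where another gene is named, it was chosen after its values were seen.

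Shares of cells with a UMI were compared after each cell was thinned without replacement to 1500 UMIs, which kept 93046 cells and left out 8642 shallower ones. Shares carry exact binomial 95% intervals, which cover counting error only, and KO and WT were compared with an exact two-sided permutation test within polarization. Its 36 arrangements allow no p below 0.0556. Shares of cells per cluster were tested with edgeR's quasi-likelihood test over the authors' 12 clusters. The share of a cluster is given only where none of its 10 leading genes was called between the groups, over all cells or within the cluster where that was tested, a rule set after the data were seen. KO and WT were also compared within each cluster that had at least 50 cells in every library.

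The tests were checked on counts simulated from the real means and library sizes, with 200 genes changed by known folds. For KO versus WT in Th17, over 13215 genes, 8%, 56%, 80% and 96% of genes changed 1.5, 2, 4 and 8 times were called, and 7.69% of the calls were false. For KO versus WT over both polarizations, over 13214 genes, the shares were 34%, 82%, 96% and 98%, with 6.63% of calls false. For Th22 versus Th17 over both genotypes, over 13207 genes, they were 44%, 80%, 92% and 98%, with 8.19% of calls false. The false share was thus above the nominal 5% in each. In simulations without any change, camera at the preset correlation gave an unadjusted p under 0.05 for 2.9% of 1000 random lists in the KO versus WT comparison over both polarizations. Genes were drawn independently there, so this does not check the test on lists of genes that vary together. Libraries were drawn independently too, while real libraries of 1 genotype and number deviated together (r = 0.80 in KO, 0.49 in WT). The simulated shares of called and false genes therefore do not cover such dependence, which matters for KO versus WT over both polarizations.

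Alternatives covered other size factors, other count filters, DESeq2 1.42.0, a replicate block, each library left out in turn, other cell filters, thinned cells, G1 cells and fits of only 4 libraries. Added after the data were seen were a covariate for UMIs per cell, leaving out clusters 2 or 7, 9 and 11 or the cells with most UMIs, a block within genotype, and sums of Th17 and Th22 libraries of 1 genotype and number. A trial clustering of the cells was made and not used. Python 3.11.15, scanpy 1.11.5 and scipy 1.17.1 were used for the cells.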

Results

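Single-cell RNA profiles were compared between WT and Gpr65 KO CD4 T cells after in vitro polarization toward Th17 or Th22. Each of the 4 groups had 2 libraries. The libraries held between 9969 and 15119 kept cells, and their median depth ranged from 2354 to 4142 UMIs per cell. Depth differed within groups: the WT Th17 libraries had medians of 2489 and 3847 UMIs, and the KO Th17 libraries 2430 and 2354. The share of cells called in G1 was 39.7% in KO Th17 replicate 1 and 51.0% in KO Th22 replicate 1, against 55.1% to 59.4% in the other 6 libraries.

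Gpr65, the targeted gene, encodes a G protein-coupled receptor that senses extracellular protons. It lies on chromosome 12 from 98268635 to 98276644 on the plus strand of mm10 (ENSMUSG00000021886). Its level was 72.5 ± 0.680 CPM (SD, n = 2) in WT Th17 and 53.7 ± 4.27 in WT Th22, against 1.56 ± 0.0180 in KO Th17 and 0.926 ± 0.0547 in KO Th22. The log2 fold change of KO over WT was -5.53 ± 0.13 (SE) in Th17 and -5.85 ± 0.13 in Th22, with edgeR adjusted p = 2.5e-06 and 2.1e-06. On cells thinned to 1500 UMIs, 6.85% to 9.33% of WT cells had a Gpr65 UMI, against 0.125% to 0.256% of KO cells. Without thinning the mean shares were 19.3% ± 3.79 in WT Th17 and 15.1% ± 1.78 in WT Th22 (SD, n = 2 each), against 0.445% ± 0.0158 in KO Th17 and 0.369% ± 0.0197 in KO Th22. All 8 libraries matched their genotype label by this gene. The labels do not say which part of the gene was deleted, so the 3' tag measures the loss of the transcript and not the extent of the deletion.

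**Figure D1:**
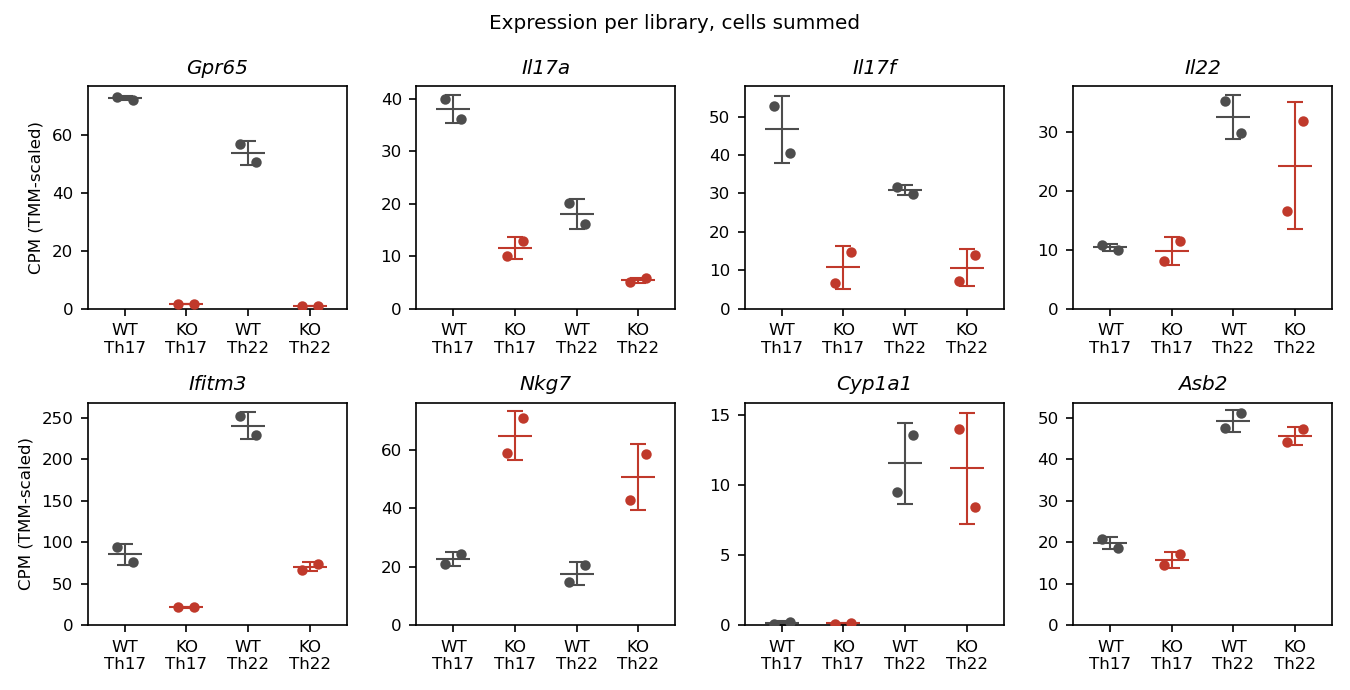
Expression of 8 genes per library in TMM-scaled CPM, summed over kept cells. Points are the 2 libraries of each group, horizontal bars the mean and error bars the SD, with WT in grey and KO in red. Il17a averaged 8.44 CPM over the 4 KO libraries, each of which was below each of the 4 WT libraries.

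The series was set up to compare gene expression between WT and KO cells. In Th17 cultures, the KO had lower transcripts of the cytokines Il17a and Il24 and of the interferon-induced membrane proteins Ifitm1 and Ifitm3. Il17a, the signature cytokine of Th17 cells, was at 11.5 ± 2.09 CPM in KO and 38.0 ± 2.67 in WT (SD, n = 2 each), a log2 fold change of -1.72 ± 0.17 (SE, edgeR adjusted p = 0.017). Ifitm1 changed by -3.02 ± 0.15, Ifitm3 by -1.99 ± 0.13 and Il24 by -1.98 ± 0.13. Ifitm1 and Ifitm3 belong to a family of similar genes, so the assignment of reads among its members is uncertain. Also lower were Klf2, a transcription factor of resting T cells (-1.20 ± 0.14), the claudin Cldn10 (-1.31), Tent5a (-1.30), Nebl (-1.19) and Sdcbp2 (-1.11). Higher in the KO were Trat1, an adaptor that associates with the T cell receptor (1.28 ± 0.15), the kinase Nek6 (1.26), Angptl6 (0.81) and the mitochondrial protease Lonp1 (0.78). In all, 25 of 13412 genes passed, 7 higher and 18 lower. Il17f had a log2 fold change of -2.12 ± 0.40 and did not pass (adjusted p = 0.11). The count fell to 8 without KO Th17 replicate 1, to 13 without KO Th17 replicate 2, to 4 and 3 without WT Th17 replicates 1 and 2 and to 6 without either WT Th22 library, and was 51 and 54 without KO Th22 replicates 1 and 2. It was 16 with only the 4 Th17 libraries fitted and 4 with the median UMIs per cell as a covariate. The Il17a call was lost without KO Th17 replicate 1 or any 1 of the 4 WT libraries and in 4 of the other alternatives, with adjusted p up to 0.22, while its log2 fold change stayed between -1.92 and -1.53.

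Among the fixed lists, naive and memory T cell genes were lower in KO Th17 cells, with 13 of 15 members lower by sign and a median log2 fold change of -0.43 (camera adjusted p = 1.6e-08). Of these members, 1 passed over all genes, Klf2, and 7 passed when adjusted over the list alone. With an estimated correlation the adjusted p was 0.17. The T cell identity list had 0 of 9 members past the test over all genes and 6 lower when adjusted over the list alone (adjusted p = 0.015, and 0.30 with an estimated correlation). The Th17 core list fell (adjusted p = 0.0054, and 0.47 with an estimated correlation), with Il17a called and 6 lower and 1 higher when adjusted over the list alone. In all, 10 of 36 lists passed at the preset correlation and 1 with an estimated correlation, the proton-sensing receptor list, whose only called member was Gpr65.

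In Th22 cultures, the KO had lower Il17a, Ifitm1 and Ifitm3, as it did in Th17 cultures. Il17a was at 5.37 ± 0.502 CPM in KO and 18.1 ± 2.86 in WT (SD, n = 2 each), with a log2 fold change of -1.75 ± 0.18 (SE, edgeR adjusted p = 0.020). Ifitm1 changed by -2.06 ± 0.14 and Ifitm3 by -1.77 ± 0.13. The endocytic adaptor subunit Ap2a2 (-1.04), Tent5a (-0.97) and Ccdc73 (-0.88) were also lower, and Nek6 (1.18) and Lonp1 (0.82) were higher. Il22, the cytokine for which these cells are named, was at 24.3 ± 10.8 CPM in KO and 32.7 ± 3.80 in WT and did not pass (-0.42 ± 0.29, adjusted p = 0.62). In all, 20 genes passed, 8 higher and 12 lower. The count was 11 without KO Th22 replicate 1, 6 without KO Th22 replicate 2, 5 without either WT Th17 library, and 1 and 4 without WT Th22 replicates 1 and 2. It was 4 with only the 4 Th22 libraries fitted, 5 with the UMI covariate and 11 on thinned cells. The Il17a call was lost in 11 of 24 alternatives, among them leaving out any 1 of the KO Th22 or WT libraries, with adjusted p up to 0.32.

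The genes called in the Th17 and in the Th22 cultures overlapped. Of 7 and 8 higher genes, 5 were shared, among them Lonp1, Nek6 and Trat1, where independent lists of these sizes would share 0.00418. Of 18 and 12 lower genes, 8 were shared, among them Gpr65, Ifitm1, Ifitm3, Il17a and Il24, where independent lists would share 0.0161. These comparisons use different libraries, but libraries of 1 genotype and number deviated together (r = 0.80 in KO and 0.49 in WT), so the lists are not independent. In KO Th22 cells the amino acid response list, which holds targets of the stress transcription factor ATF4, rose, with 20 of 20 members higher by sign and a median of 0.40. None of its members passed over all genes and 8 passed when adjusted over the list alone (camera adjusted p = 4e-10, and 0.055 with an estimated correlation). The interferon response list rose as well (adjusted p = 7.9e-06), with 0 of 36 members called over all genes, 2 when adjusted over the list alone, and adjusted p = 0.59 with an estimated correlation. In this comparison 10 of 36 lists passed at the preset correlation.

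Over both polarizations, KO cells had lower Il17a and Il17f and higher Spp1, Ccl4, Cd74 and Nkg7 than WT cells. Il17a (chromosome 1, 20730905 to 20734496) had a log2 fold change of -1.74 ± 0.11 (SE, edgeR adjusted p = 0.00025). Its neighbour Il17f (chromosome 1, 20777146 to 20790617) had -1.82 ± 0.28 (adjusted p = 0.015), at 10.7 ± 4.29 CPM in KO and 38.7 ± 10.5 in WT (SD, n = 4 each). Ifitm3 changed by -1.88 ± 0.09, and the extracellular matrix gene Ecm1 (-1.16), Tent5a (-1.13), the leukotriene receptor Ltb4r1 (16.4 CPM in KO and 33.0 in WT), Nebl (-0.99), Sdcbp2 (-0.95) and Cldn10 (-0.89) were lower too. Among called genes with a mean of at least 10 CPM and no overlap between the KO and WT libraries, the largest rise was in Spp1, which encodes osteopontin (2.59 ± 0.37), followed by the chemokine Ccl4 (1.75 ± 0.35), Cox6a2 (1.57), the invariant chain Cd74 (1.53 ± 0.27), the cytotoxic granule gene Nkg7 (1.52 ± 0.14), the stress gene Nupr1 (1.35), Trat1 (1.33), Cth (1.32), Nek6 (1.22) and Bcl2a1b (1.13). Bcl2a1b and Ccl4 have close paralogs, so the assignment of their reads is uncertain. In all, 393 genes passed, 189 higher and 204 lower.

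The Th1 transcription factor Tbx21 was higher in the KO (1.16 ± 0.22, edgeR adjusted p = 0.031) at a low level of 3.96 ± 1.31 CPM against 1.76 ± 0.748 (SD, n = 4 each). Other helper cell genes did not pass over both polarizations. The log2 fold changes were -0.26 ± 0.20 for Il22, 0.15 ± 0.21 for Ahr, -0.36 ± 0.66 for Ifng, 0.68 ± 0.39 for Csf2, 0.29 ± 0.14 for Il23r, 0.51 ± 0.22 for Gzmb, 0.32 ± 0.24 for Tnf, 0.73 ± 0.37 for Il2 and -0.09 ± 0.27 for Cyp1a1. Il10 and Foxp3 were below the count filter. Where Th17 and Th22 libraries of 1 genotype and number were summed, 2 against 2, 6 genes passed, all 6 among the 393, and Il17a had adjusted p = 0.055. If libraries of 1 number share an animal, that count is the one with independent units. The count of 393 became 148 without KO Th17 replicate 1, 260 without KO Th17 replicate 2, 229 without KO Th22 replicate 2, 56 and 92 without WT Th17 replicates 1 and 2, and 131 and 50 without WT Th22 replicates 1 and 2, and it was 206 on thinned cells. The Il17f call was lost without either WT Th17 library, without WT Th22 replicate 2 and in the summed fit, with adjusted p up to 0.26.

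Among the fixed lists over both polarizations, the ATF4 list rose in the KO, with 19 of 20 members higher by sign and a median of 0.33. Of these, 5 passed over all genes and 12 when adjusted over the list alone. They include the enzymes of asparagine and serine synthesis Asns (0.61 ± 0.09), Phgdh (0.51 ± 0.07), Psph (0.59 ± 0.09) and Psat1 (0.46 ± 0.08). The camera adjusted p was 8e-09, and 0.11 with an estimated correlation. Naive and memory T cell genes fell, 5 of 15 over all genes and 9 when adjusted over the list alone, among them Tcf7 (-0.56 ± 0.10), Lef1 (-0.37 ± 0.08) and Klf2 (-0.80 ± 0.16), with adjusted p = 6.7e-06, and 0.28 with an estimated correlation. Th17 core genes fell, 5 of 18 over all genes, with 8 lower and 2 higher when adjusted over the list alone. Besides Il17a and Il17f, these were led by Tmem176a (-1.02 ± 0.11) and Hif1a (-0.47 ± 0.07). The median was -0.10, with adjusted p = 3.9e-05, and 0.29 with an estimated correlation.

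The list of genes linked to pathogenic Th17 cells rose (camera adjusted p = 0.028, and 0.51 with an estimated correlation), with 4 of 18 members higher and 1 lower over all genes, and 6 higher and 4 lower when adjusted over the list alone. Its call was lost on thinned cells (adjusted p = 0.052), among G1 cells (0.067) and without clusters 7, 9 and 11 (0.052). Its leading members were the chemokines Ccl3 (2.08 ± 0.33) and Ccl4, Lgals3 (0.87 ± 0.15) and Tbx21, and Ccl3 was at 8.31 CPM in KO. Interferon response genes rose, with Ifih1 (0.70 ± 0.08), Isg15 (1.05 ± 0.18) and Irf7 (0.59 ± 0.12) higher and Ddx58 (-0.42 ± 0.07) lower among 36 members, and 7 higher and 1 lower when adjusted over the list alone (adjusted p = 0.00011, and 0.51 with an estimated correlation). The mitochondrial respiration list rose with a median of 0.08 and 2 of 34 members called, Atp5g1 (0.44 ± 0.07) and Uqcrq (0.37 ± 0.07), and 3 when adjusted over the list alone, with adjusted p = 0.0095, and 0.57 with an estimated correlation. The endoplasmic reticulum stress list rose with 0 of 16 members called, and 6 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0078, and 0.30 with an estimated correlation).

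S phase genes were higher in the KO, with 38 of 42 members higher by sign and 0 called over all genes or when adjusted over the list alone (camera adjusted p = 0.00039, and 0.51 with an estimated correlation), and G2/M genes were lower, with 2 of 52 called, Lbr (-0.49 ± 0.08) and Gas2l3 (-0.69 ± 0.14), the same 2 as when adjusted over the list alone (adjusted p = 0.030, and 0.82 with an estimated correlation). The G2/M call was lost on thinned cells (adjusted p = 0.095), and among cells called in G1, a call that uses these lists, the direction turned (median 0.41, adjusted p = 0.00033). The S phase call was lost among G1 cells (adjusted p = 0.11). The share of cells called in S was 36.4% in KO Th17 replicate 1 and 27.4% to 27.9% in the other KO libraries. In the WT libraries it was 22.8% to 26.0%, so each KO library was above each WT library. In G2/M it was 23.9% and 21.1% in replicate 1 of KO Th17 and KO Th22, and 14.1% and 12.7% in replicate 2. The WT libraries had 18.3% to 20.7% in G2/M, so for this phase the KO replicates lay on both sides of WT. B cell markers were lower in the KO, with Ighm (-0.47 ± 0.08) called among 5 tested members and 2 when adjusted over the list alone (adjusted p = 0.027, and 0.51 with an estimated correlation), and so were stromal and endothelial markers, with Pecam1 (-0.67 ± 0.13) called among 3 and 2 when adjusted over the list alone (adjusted p = 0.012, and 0.28 with an estimated correlation). The B cell call was lost on thinned cells (adjusted p = 0.21), among G1 cells (0.18) and without the cells with most UMIs (0.10). With Gpr65 in the proton-sensing receptor list, 12 of 36 lists passed at the preset correlation, 1 with an estimated correlation and 8 with fry. Lists for lysosomal genes, the V-ATPase, glycolysis, aryl hydrocarbon receptor targets and cyclic AMP response genes were among the 24 that did not pass.

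**Figure D2:**
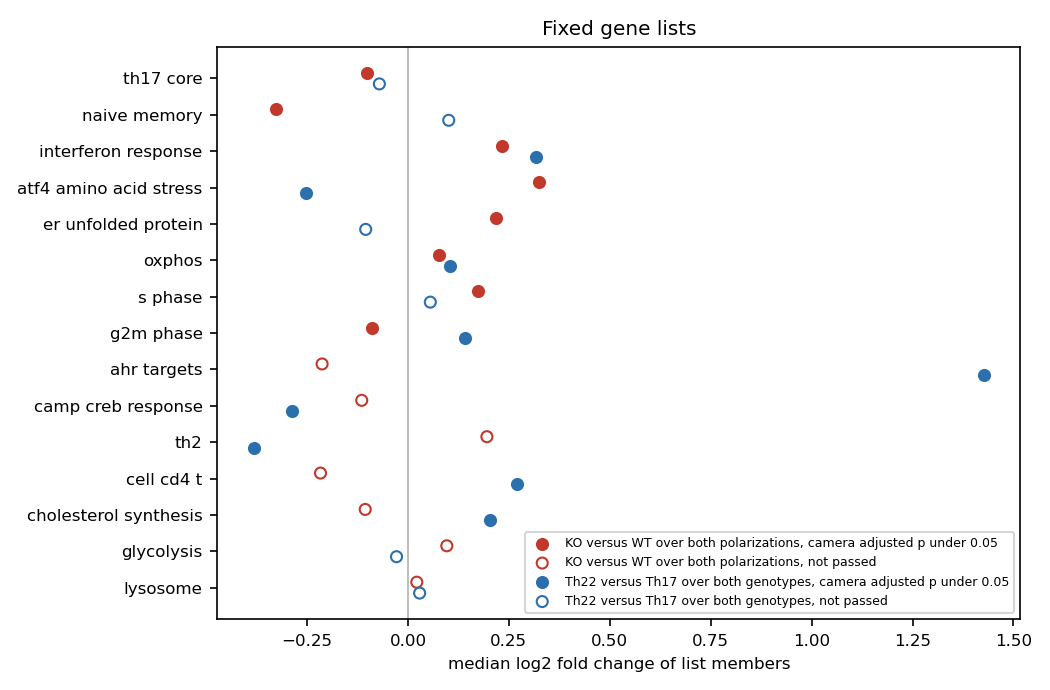
Median log2 fold change of the members of 15 of the fixed gene lists for KO over WT (red) and Th22 over Th17 (blue), each over 8 libraries. Filled circles passed camera at the preset correlation with adjusted p under 0.05 and open circles did not. The aryl hydrocarbon receptor target list had a median of 1.43 between Th22 and Th17 and -0.21 between KO and WT.

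The share of cells with an Il17a UMI, on cells thinned to 1500 UMIs, was 0.707% ± 0.0591 in KO Th17 and 1.90% ± 0.309 in WT Th17 (SD, n = 2 each), and 0.236% ± 0.0339 in KO Th22 and 1.04% ± 0.0783 in WT Th22. For Il17f the shares were 1.13% ± 0.544 and 4.04% ± 0.889 in Th17 and 0.868% ± 0.192 and 2.66% ± 0.228 in Th22. Each KO library was below each WT library of its polarization for both genes, and the exact permutation p was 0.0556, the smallest this design allows, or 0.144 after adjustment over 13 shares. Without thinning, KO minus WT was -1.68 percentage points for Il17a and -3.86 for Il17f. No cluster was known to lack these cytokines, so the share that free RNA gives was not measured for them. Shares for Il22 (KO minus WT -0.220 percentage points, exact p = 0.333) and Gzmb (5.06, exact p = 0.444) did not separate the genotypes.

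The authors' clusters were described by their leading genes. Cluster 3 and cluster 10 were G2/M-like (Nusap1, Birc5, Mki67 and Top2a, and Cenpf, Hmmr and Ube2c), and cluster 8 was interferon-response-like (Isg15, Ifit1, Ifih1, Oasl1 and Ifit3). Cluster 7, led by gamma-delta receptor and cytotoxic genes such as Trdc, Tcrg-C4, Gzmc and Klrd1, held 1.59% to 3.30% of the cells of a library and stayed unnamed, as did the others. The shares of clusters 3, 10 and 11 could be compared between groups. Those of the other 9 are not given, because leading genes were called between the groups within the cluster or over all cells, such as Klf2 for cluster 0, Crip2 and S100a6 for cluster 6 and Il17a, Il24, Ifitm1, Ifitm3 and Il22 for cluster 2. No share of the 3 compared passed in any comparison. The lowest adjusted p by edgeR was 0.38 between KO and WT, for cluster 10 in Th17. Between Th22 and Th17 it was 0.32, for cluster 10 over both genotypes. Cluster 10 had a median of 7216.5 UMIs per cell, and its share went with library depth. It held 0.287% to 0.562% of cells in libraries with a median up to 2627 UMIs, and 1.29% to 2.69% in those from 3669.5 UMIs. Its share is therefore not separate from depth. Within clusters, Ifitm3, a leading gene of cluster 2, was called lower in the KO in all 10 clusters tested, by -2.47 to -0.95, and Gpr65 in all 9 where it was tested. Nkg7, a leading gene of cluster 7, was called higher in 8 of 10 clusters, Nupr1 in 7 of 10 and Ecm1 was called lower in 9 of 10. Calls were fewer for Spp1 and Cd74 (4 of 9 each) and for Ccl4 (1 of 8). Il17a was called lower in 3 of 5 and Il17f in 2 of 7. They were at 131 and 161 CPM in cluster 2, which they lead, and 2.42 and 5.90 CPM over the other clusters pooled. Among those, cluster 11 had 30.8 and 75.4 CPM. What free RNA from other clusters adds to these values was not measured.

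Th22 was compared with Th17 in WT cells and in KO cells. In WT cells, Th22 cultures had higher Ifitm1 (2.12 ± 0.14), Ifitm3 (85.3 CPM in Th17 and 241 in Th22), Asb2 (1.32 ± 0.12), Rcc1l (1.19), Dkkl1 (1.18), the heme synthesis enzyme Cpox (1.11) and Atp10a (1.05), and lower Il24 (-1.80 ± 0.13), Serpinb5 (-1.11), the polyamine synthesis enzyme Odc1 (-1.08) and the integrin Itga3 (-1.01). Cyp1a1, the classic target of the aryl hydrocarbon receptor, was at 0.148 ± 0.128 CPM in WT Th17 and 11.5 ± 2.91 in WT Th22 (SD, n = 2 each). In all, 20 genes passed by edgeR, 13 higher and 7 lower. By edgeR the count was 0 without WT Th17 replicate 1, WT Th17 replicate 2 or WT Th22 replicate 2, and 4 without WT Th22 replicate 1. With only the 4 WT libraries fitted it was 226, and 12 with the UMI covariate. With all libraries 1183 genes had an unadjusted p under 0.05 and DESeq2 called 146. Of the fixed lists, 9 of 36 passed at the preset correlation and 2 with an estimated correlation, the aryl hydrocarbon receptor targets (4 of 10 members called and 7 when adjusted over the list alone, camera adjusted p = 6.7e-34, and 0.017) and the ATF4 list, which fell (adjusted p = 5.8e-11, and 0.046) with 0 of 20 members called over all genes and 4 when adjusted over the list alone.

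In KO cells, Th22 cultures had higher Ifitm1 (3.08 ± 0.15), Tiparp (1.94 ± 0.21), Ifitm3 (1.71 ± 0.13), Asb2 (1.53 ± 0.12) and Serpinb1a (0.83 ± 0.10), and lower Itga3 (-1.42 ± 0.12). Cyp1a1 rose from 0.112 ± 0.0213 to 11.2 ± 3.95 CPM (SD, n = 2 each). In all, 16 genes passed by edgeR, 10 higher and 6 lower, of which 7 and 4 were also called in WT, among them Asb2, Cyp1a1, Ifitm1, Ifitm3, Il24 and Itga3. Independent lists would share 0.00969 and 0.00313. The count was 9, 8 and 10 without KO Th17 replicate 1, KO Th17 replicate 2 and KO Th22 replicate 2, and 6 without any 1 WT library. It was 0 with only the 4 KO libraries fitted and 2 with the UMI covariate, while with all libraries edgeR gave 1451 genes an unadjusted p under 0.05 and DESeq2 called 181. The T cell identity list rose, with 0 of 9 members called over all genes and 7 when adjusted over the list alone (camera adjusted p = 2.2e-06, and 0.11 with an estimated correlation). Of 12 lists past the preset test, 1 passed with an estimated correlation, the aryl hydrocarbon receptor targets, with 4 of 10 members called and 6 when adjusted over the list alone (adjusted p = 0.020).

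Over both genotypes, Th22 cells had higher Il22 and aryl hydrocarbon receptor targets and lower Il17a than Th17 cells. Il22 (chromosome 10, 118204942 to 118210047) was at 28.5 ± 8.17 CPM in Th22 and 10.1 ± 1.46 in Th17 (SD, n = 4 each), a log2 fold change of 1.48 ± 0.21 (SE, edgeR adjusted p = 0.011). Il17a changed by -1.08 ± 0.11 (adjusted p = 0.0027), and Il17f did not pass (-0.32 ± 0.27). Tiparp (1.70 ± 0.16), Asb2 (1.42 ± 0.09), Cldnd1 (1.34), the transcriptional repressor Hic1 (1.16), Plac8 (1.10), Rcc1l (1.09), Cpox (1.08), Dkkl1 (1.02) and Rcbtb2 (0.89) were higher. Lower were Hamp, which encodes the iron hormone hepcidin (-2.81 ± 0.29), the chemokine Ccl5 (-1.73 ± 0.27), Itga3 (-1.21), Myb (-1.14), Inhba (-1.10), Pdgfb (-1.08), Ramp1 (-1.05), Atf3 (-0.97), Cd274, which encodes PD-L1 (-0.97), and Pik3ap1 (-0.94). Gpr65 itself did not pass between Th22 and Th17 in WT (-0.43 ± 0.10, adjusted p = 0.23). In all, 260 genes passed, 136 higher and 124 lower. Within clusters, Asb2 and Tiparp were called higher in all 9 clusters tested and Hamp lower in 6 of 7. Ahr, Ifng, Csf2, Il23r, Gzmb, Tbx21, Tnf and Il2 did not pass.

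The count of 260 became 129 and 172 without KO Th17 replicates 1 and 2, 63 and 86 without WT Th17 replicates 1 and 2, and 76 and 54 without WT Th22 replicates 1 and 2, and 86 with the median UMIs per cell as a covariate. With a replicate block within genotype it became 1592, and the counts in WT and in KO became 1733 and 2269. Libraries of 1 genotype and number deviated together (r = 0.80 in KO and 0.49 in WT), which the fits without this block leave out. The Il22 call was lost without either WT Th17 library or WT Th22 replicate 2, with adjusted p up to 0.063.

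The aryl hydrocarbon receptor target list rose most, with 6 of 10 members called, also when adjusted over the list alone, and a median of 1.43 (camera adjusted p = 1e-40, and 0.0033 with an estimated correlation). Its members Cyp1a1 (6.39 ± 0.33) and Cyp1b1 (6.70 ± 0.51) were near the floor in Th17, at 0.130 and 0.0552 CPM, so their folds rest on few counts there, while the repressor Ahrr rose by 2.27 ± 0.19. The ATF4 list fell, with 2 of 20 called, Atf3 and Psat1 (-0.41 ± 0.08), and 11 when adjusted over the list alone (adjusted p = 5.9e-10, and 0.085 with an estimated correlation). Interferon response genes rose, with 3 of 36 called, among them Ddx58 (0.71 ± 0.07) and Ifi27l2a (0.59 ± 0.10), and 17 higher and 2 lower when adjusted over the list alone (adjusted p = 5.8e-08, and 0.37 with an estimated correlation). T cell identity genes rose, led by Cd3g (0.53 ± 0.08) and Cd3d (0.39 ± 0.08), the 2 of 9 called, with 5 when adjusted over the list alone (adjusted p = 9.9e-06, and 0.14 with an estimated correlation).

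Th2 genes fell, with Ccr8 (-1.61 ± 0.28) and Gata3 (-0.61 ± 0.11) called of 8 and 3 when adjusted over the list alone (camera adjusted p = 0.00027, and 0.10 with an estimated correlation). Cyclic AMP response genes fell, with Sik1 (-0.97 ± 0.15) and Nr4a3 (-1.08 ± 0.20) called of 25 and 5 when adjusted over the list alone (adjusted p = 5.3e-05, and 0.25 with an estimated correlation). The list for less pathogenic Th17 cells passed as lower with a median of 0.01 and a mean of -0.17, so its members moved apart: Il24 (-1.78 ± 0.09) and Il1rn (-1.74 ± 0.15) fell and Il6st (0.49 ± 0.09) rose, with 2 lower and 3 higher when adjusted over the list alone (adjusted p = 0.0012, and 0.12 with an estimated correlation). Dendritic cell markers were lower, with H2-Eb1 (-0.91 ± 0.15) called of 6, also when adjusted over the list alone (adjusted p = 0.0095, and 0.30 with an estimated correlation). Lists for cholesterol synthesis, with Fdps (0.34 ± 0.07) called of 22 and 4 when adjusted over the list alone, respiration and G2/M rose and the activation list fell, with adjusted p = 0.0012, 0.0012, 0.0012 and 0.029, or 0.70, 0.47, 0.70 and 0.70 with an estimated correlation. On thinned cells the G2/M and activation calls were lost (adjusted p = 0.16 and 0.054), and among G1 cells the G2/M direction turned (median -0.41, adjusted p = 7.7e-08). Of the respiration, G2/M and activation lists 0 members were called by edgeR over all genes or when adjusted over the list alone. In all, 12 of 36 lists passed at the preset correlation, 1 with an estimated correlation and 6 with fry.

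The interaction asked whether the genotype effect differed between Th17 and Th22. By edgeR 0 of 13412 genes passed, with 566 at an unadjusted p under 0.05, and DESeq2 called 6. With a replicate block within genotype edgeR called 550, 206 higher and 344 lower, so the count of 0 holds for the fit without that block. The labels do not say whether libraries of 1 genotype and number belong together. They did deviate together (r = 0.80 in KO and 0.49 in WT), which the fit without the block leaves out. For Il17a the difference between the effects was -0.02 ± 0.24 on the log2 scale, for Il17f 0.59 ± 0.55 and for Il22 -0.34 ± 0.42. With that block Il17f passed (0.58 ± 0.12, adjusted p = 0.020) and Il17a and Il22 did not (adjusted p = 0.96 and 0.18). Klf2, lower in KO Th17 and at -0.40 ± 0.14 in KO Th22 (adjusted p = 0.33), had a difference of 0.80 ± 0.20 that did not pass. The camera test passed 5 lists for the interaction at the preset correlation and 0 with an estimated correlation or fry.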

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

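Of the tests in this part, the fit with a replicate block was chosen after results were seen. These results were singled out because the genotype effect differed between Th22 and Th17 by a test of the difference itself. Camera on the interaction, at the preset correlation, gave adjusted p = 0.00381 for natural killer cell markers, 0.00381 for cyclic AMP response genes, 0.0156 for naive and memory T cell genes, 0.0306 for cytotoxic genes and 0.0442 for dendritic cell markers. With an estimated correlation each of the 5 had adjusted p = 0.485, and 0 genes passed the interaction by edgeR, where 566 had an unadjusted p under 0.05 and DESeq2 called 6. With a replicate block within genotype edgeR called 550, and the list tests were run without that block. Natural killer markers, with 4 tested, had a median difference of 2.28, led by Gzma, at -3.82 ± 0.86 (log2, SE) between KO and WT in Th17 and -0.37 ± 0.63 in Th22. Gzma is also a member of the cytotoxic list, so those results are not independent, and it was at 0.318 CPM in KO Th17, near the floor. The difference was above 0 for 8 of 8 cytotoxic genes. Cyclic AMP response genes were higher by sign in 21 of 25, led by Gem (difference 0.63 ± 0.21), and naive and memory genes in 13 of 15, led by Klf2 (0.80 ± 0.20) and Satb1 (0.33 ± 0.13). Dendritic cell markers were lower by sign in 5 of 6, led by Xcr1 (-1.67 ± 0.67), which was at 0.285 CPM over the KO libraries. Groups of 2 libraries were too small to test any library as standing apart from its group.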

How the results depend on the processing

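The UMI covariate, the sums over polarizations, the block within genotype and leaving out the cells with most UMIs were chosen after the data were seen. No call of a gene changed sign in any alternative, and of 5672 values for 237 genes and comparisons 4783 kept their side of the threshold, 847 lost the call and 42 gained one. In the order KO versus WT in Th17, in Th22 and over both, and Th22 versus Th17 in WT, in KO and over both, the counts of 25, 20, 393, 20, 16 and 260 genes became 200, 144, 942, 146, 181 and 552 with DESeq2, whose interaction count was 6. At least 10 CPM in 2 libraries gave 13 in Th17, 185 over both, and 10, 10 and 146 between Th22 and Th17, with fewer genes tested. No count filter gave 42 in Th17, 38 in WT and 32 in KO. G1 cells gave 43 in Th17 and 40 in KO, thinned cells 11 in Th22 and 206 over both, stricter cell filters 7 in Th22, and leaving out the cells with most UMIs 11 in Th22. The UMI covariate gave 4, 5, 463, 12, 2 and 86 in that order. Only the 4 libraries concerned gave 16, 4, 226 and 0 for Th17, Th22, WT and KO, with 2 residual degrees of freedom fewer. Sums over polarizations gave 6. With the replicate block the counts were 9, 6, 6 and 7 in Th17, Th22, WT and KO. Libraries of 1 genotype and number deviated together (r = 0.80 in KO, 0.49 in WT) and moved apart across genotypes (r from -0.45 to -0.37, across 12574 genes). What the numbers stand for is not given, and no pairing across genotypes was fitted beyond the block. A replicate block within genotype gave 1733, 2269, 1592 and 550 for WT, KO, both and the interaction. Camera with an estimated correlation passed 1, 1, 1, 2, 1, 1 and 0 lists, the interaction last, and fry 3 in Th17, 2 in Th22, 5 in WT, 5 in KO, 6 over both genotypes and 0. Unthinned shares differed by -1.68 points for Il17a and -3.86 for Il17f. The cause of these moves was not tested unless stated.

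Leaving out 1 library in turn gave 3 to 54 genes in Th17, 1 to 14 in Th22, 50 to 541 over both, 0 to 28 in WT, 6 to 12 in KO, 54 to 247 over both genotypes and 0 to 0 for the interaction. The lone library left in a group is assumed to vary like the others. Gpr65 stayed between -5.54 and -5.52 in Th17, -5.93 and -5.76 in Th22 and -5.73 and -5.62 over both. The Il17a share differed by -1.11 to -0.89 points and the Il17f share by -2.66 to -2.04. The doublet caller removed 2 cells, so that alternative is void, and other clustering resolutions were not run because the clusters are the authors'. What depth limits among genes of low level was not tested, and 164 of the 393 calls between KO and WT lay under 10 CPM.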

Other observations

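Of the tests in this part, those of Il17a and Il17f, of the genes near Gpr65, of replicate 1 against 2 and without clusters 7, 9 and 11 were chosen after results were seen. The KO libraries of replicate 1 and replicate 2 differed from each other in the same way in Th17 and in Th22. With polarization as a term, edgeR called 4931 of 12955 genes between KO replicates 1 and 2 and 1523 of 13088 between WT replicates 1 and 2, both at 0.05 after adjustment. Glycolysis genes were called higher in KO replicate 2 in 16 of 20 (median log2 0.70) and lower in WT replicate 2 in 12 of 20 (median -0.26). Hypoxia genes were higher in 13 and lower in 2 of 18 in the KO and lower in 10 and higher in 1 of 18 in WT. Cholesterol synthesis genes were higher in 15 of 22 in the KO and lower in 9 of 22 in WT, and camera with an estimated correlation gave adjusted p = 0.66 in the KO and 0.89 in WT for each of these 3 lists. Mitochondrial transcripts were called higher in KO replicate 2 in 11 of 13 and dissociation stress genes in 7 of 12, and gamma-delta T cell markers lower in 4 of 5 (camera adjusted p = 1.2e-06, 0.0040 and 8.3e-05, and 0.66 each with an estimated correlation). G2/M genes were called lower in KO replicate 2 in 37 of 52 (camera adjusted p = 5e-12, and 0.66 with an estimated correlation).

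The source of that difference within the KO was weighed. On cells thinned to 1 depth 4191 genes were called, among G1 cells 3565, and without clusters 7, 9 and 11 4852. Each was above a level set before these tests were run, though the tests were chosen after results were seen. The counts among G1 cells and without those clusters argue against cycling cells or those clusters as the whole cause. Thinned counts are scaled to each library's total like the others, so thinning could change little and does not decide on depth per cell. A difference between animals, or in stress or RNA quality, may lie behind it and stays open. Such a difference would have to be shared by the Th17 and Th22 cultures of 1 number, which were separate cultures. The labels do not say what the replicate numbers stand for. No biological explanation was tested.

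The lower Il17a and Il17f in the KO were weighed against technical sources. The log2 fold change of Il17a was -1.75 on thinned cells. Summed counts are scaled to each library's total, so thinning could change little and does not decide on depth per cell. The fold change was -1.74 without clusters 7, 9 and 11. Il17a was at 5.34, 4.70 and 30.8 CPM in these small clusters and at 131 CPM in cluster 2. Leaving them out could therefore change little and decides nothing, and the part played by cluster 2 was not weighed here. Between replicates 2 and 1 Il17a differed by 0.29 ± 0.10 in the KO and -0.23 ± 0.06 in WT. Both values are small beside its fold between the genotypes. For Il17a this argues against a difference between replicates of 1 genotype as the source. A difference that separates all KO from all WT cultures cannot be told apart from genotype here. Il17f differed by 1.03 ± 0.10 between KO replicates, a large part of its -1.82, so a difference between cultures may contribute to Il17f. That the loss of Gpr65 lowers both cytokines remains a hypothesis for these libraries.

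Knockout lines can keep DNA of the donor strain around the target. Within 10 Mb of Gpr65, 3 of 63 tested genes passed between KO and WT, 4.76% with an exact interval of 0.993% to 13.3%, against 2.94% of 13170 genes elsewhere (Fisher's exact p = 0.435). They were D130020L05Rik (0.89), Gm20069 (-1.20) and Ifi27 (0.98), named after their values were seen. A contribution of flanking DNA is possible and cannot be told apart from the loss of Gpr65 here, because few genes lie in the window. Over the real grouping of libraries, 393 genes were called by genotype against at most 1 gene in the other 33 of 34 splits, and 260 by polarization against at most 14, each real count being the 1 of its 34 splits that large. These splits cannot exclude chance for either count. The other splits mix the real groups, so any real difference adds to their spread and few calls were likely there. Splits that keep the other factor balanced allow no share below 0.0556, even if the 8 libraries are independent. Libraries of 1 genotype and number deviated together (r = 0.80 in KO and 0.49 in WT), and if a number marks an animal, genotype has 2 units against 2, too few splits for a share under 0.05, and the summed fit called 6 genes.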
